A study of Mus musculus with 12 samples.

How the data were processed

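The authors pooled heart RNA, labelled 100 ng per sample with the 3′ IVT Express protocol and hybridised it to 1 array per pool. The design text names MAS5 as their normalization and the processing notes name RMA in Affymetrix Expression Console 1.1. The deposited values are on a log2 scale from 1.70 to 14.75, printed with 2 decimals, with nearly equal quartiles in every array. They were taken as RMA values, and MAS5 signals put on a log2 scale were not excluded by a test. They were used as deposited, so that the pseudocount alternatives fixed for linear values did not apply. No array was a copy of another (0 identical among 66 pairs).

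Of 45101 probe sets, 64 are controls and were kept for quality checks. The array annotation gives exactly 1 gene for 34945 of the other 45037, several genes for 932 and no gene for 9160. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays. Genes with a mean at or below the median of all probe set means (5.04) were left out, 6367 of them, which leaves 11826 tested.

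The test was limma 3.58.1 in R 4.3.3: a linear model with a mean for each of the 4 groups over all 12 arrays, empirical Bayes variances without trend, and contrasts for diabetes against control at each day, for the difference between those effects (the interaction) and for E15.5 against E13.5 in each condition. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at adjusted p < 0.05. The median SE of a difference was 0.10 and the median 95% interval ±0.22 (1.16-fold), or ±0.31 (1.24-fold) for the interaction. A self-test shifted 200 of 11826 simulated genes, which varied independently of each other and without the structure of the pools. Single values per array were compared by exact permutation tests, two-sided. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

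A total of 34 gene lists with 622 different genes covered heart muscle, signalling, metabolism, stress, matrix, and the cell types and sample qualities that a heart pool could hold. Of these genes, 589 had a probe set of their own and 529 were tested, in the 33 lists with at least 3 tested genes. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg over the lists of a contrast, beside camera with an estimated correlation, which called no list in any contrast, and fry. Fits of the lists without some arrays or with other processing used the preset correlation alone. Fry, which asks whether a list's own genes move one way, called 0 lists in the 3 diabetes contrasts, 3 in control hearts with age (BMP and TGF-beta, Wnt, cushion and valve) and 6 in diabetes hearts with age (BMP and TGF-beta, cushion and valve, Notch, fibroblast, extracellular matrix, cell cycle). Its mixed form, which asks whether genes of a list change in either direction, called 0 lists at E13.5, 1 at E15.5 (ventricular markers, adjusted p = 7.0e-04), 0 for the interaction, 21 in control hearts with age and 23 in diabetes hearts with age.

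The genes named follow a rule. For the 2 diabetes contrasts it takes up to 10 called genes per direction with the largest change and groups that do not overlap, and for the other contrasts up to 5. Directions with fewer than 5 called genes were filled to 5 by the smallest p. Genes with clone, RIKEN, Gm or LOC names are counted and not named. Up to 4 members with the smallest p stand for each described list. Nppa, Myh6, Myh7, Vegfa, Slc2a1, Nkx2-5, Gata4, Hbb-y and Xist are given for each contrast. Groups, contrasts, lists, this rule and all alternatives except those said to have been chosen later were fixed before the data were examined.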

Results

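Gene expression was measured in pooled hearts of Swiss Albino mouse embryos with the Affymetrix Mouse Genome 430 2.0 array. The 12 arrays form 4 groups of 3, control and diabetes hearts at embryonic day 13.5 (E13.5) and control and diabetes hearts at E15.5. Diabetes hearts were those of malformed embryos whose dams had been made diabetic with streptozotocin, a toxin of pancreatic beta cells, given at 75 mg per kg body weight on 3 days. Blood glucose exceeded 16 mmol/l in these dams. Control hearts were those of normal embryos, which the protocol takes from diabetic as well as non-diabetic dams without saying which array holds which. A diabetes effect below means diabetes minus control hearts, in which the dam's diabetes and malformation cannot be told apart. By the protocol each array held the RNA of several embryos from several litters, so a p-value here measures differences against the spread between pools. Values are log2 intensities, with a median per array of 5.0 to 5.08 over all probe sets. Arrays give no count or depth, and their number limits the precision. Of 18193 genes with a probe set of their own, the 11826 with a mean above 5.04 were tested.

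The embryonic day was the main difference between the arrays. The first principal component held 41.5% of the variance and put the E13.5 arrays at −14.6 to −11.9 and the E15.5 arrays at 3.14 to 26.1. Pairs of arrays within a group correlated across genes at r = 0.980 to 0.996. The E15.5 pools also differed in content. The mean of the embryonic globins Hbb-y, Hbb-bh1 and Hba-x, made by primitive red cells, was 12.25 to 13.15 in the E13.5 arrays. At E15.5 it was 9.84, 11.46 and 9.74 in control replicates 1 to 3 and 11.08, 8.31 and 11.91 in diabetes replicates 1 to 3. The group means of these globins at E15.5 lay 0.08 apart (exact permutation test, two-sided p = 1, where 3 against 3 arrays allow no p below 0.10). The fetal liver gene Afp was at 9.69 in E15.5 control replicate 2 and at 6.18 or lower in the other 11 arrays. In E15.5 diabetes replicate 2 Xist, the RNA of the inactive X chromosome, was at 6.13 and the mean of 3 Y-linked genes at 7.74, as in a pool of males. In E15.5 diabetes replicate 3 Xist was at 12.48 and the Y-linked mean at 2.34, as in a pool of females, and the mean of the skeletal muscle markers reached 6.77 there against 6.19 or lower elsewhere. These readings leave open how many embryos the 2 pools held. In E15.5 diabetes replicate 1 the means of the markers of lung and thymus epithelium (5.89) and of the leukocyte markers (7.05) were the highest of the 12 arrays. In the 10 arrays other than E15.5 diabetes replicates 2 and 3 Xist (9.90 to 12.03) and the Y-linked genes (5.81 to 7.10) were both well above those low values. The log2 ratio of 3′ to 5′ Actb probe sets, a sign of RNA quality, lay between 0.86 and 1.16 in all 12 arrays.

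**Figure D1:**
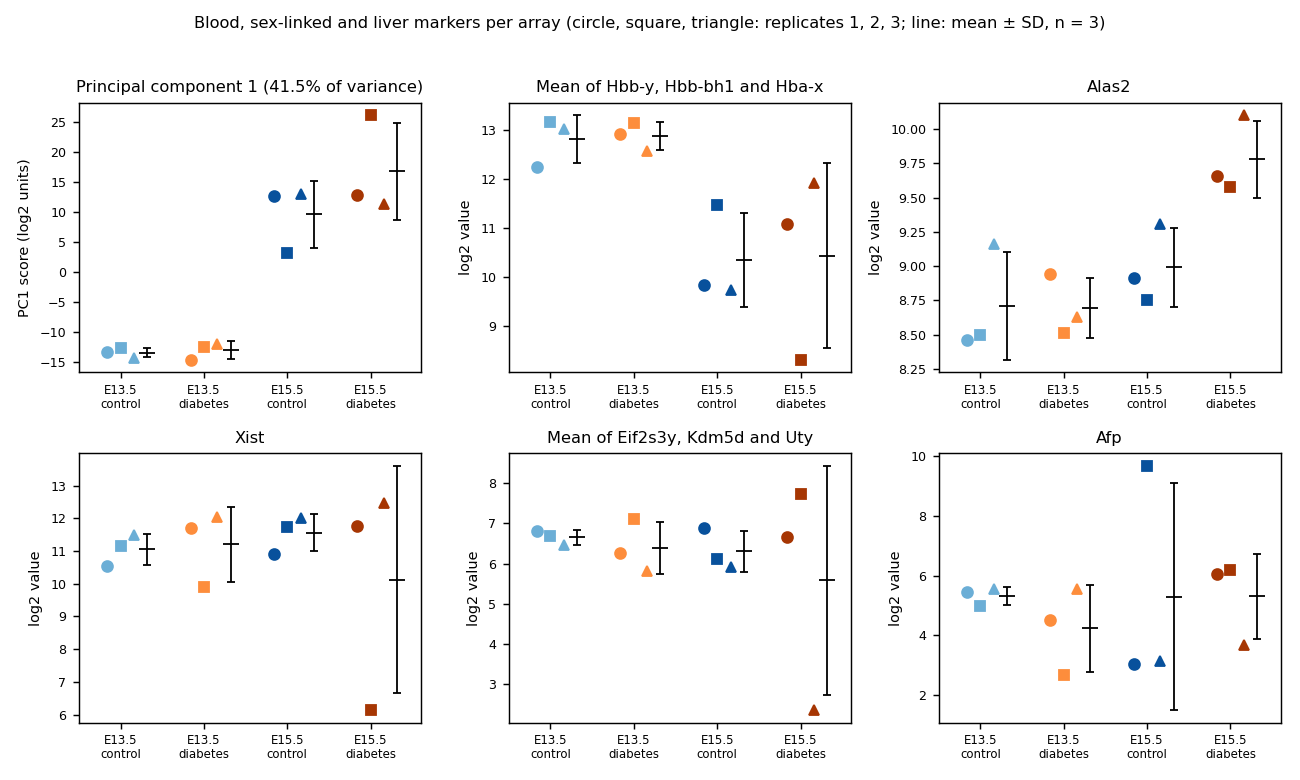
Values per array (points, 1 per array, grouped by day and condition; log2 except the component score): first principal component, mean of the embryonic globins, Alas2, Xist, mean of the Y-linked genes, and Afp. E15.5 diabetes replicate 2 has the lowest globin mean (8.31) and E15.5 control replicate 2 has the highest Afp (9.69).

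The first comparison asked how hearts of malformed embryos differed from control hearts at E13.5. No gene passed the test. The genes of heart muscle and of cardiac identity had nearly equal levels in the groups. Nppa, the atrial natriuretic peptide gene, was at 13.50 ± 0.04 in control and 13.55 ± 0.05 in diabetes hearts (SD, n = 3 arrays each, log2). The myosin heavy chain genes Myh6 and Myh7 differed by −0.04 and 0.00, and the transcription factor genes Nkx2-5 and Gata4 by 0.11 and 0.03 (diabetes minus control, SE 0.09 to 0.10). Vegfa, the vascular growth factor gene, differed by 0.13 (SE 0.23), the glucose transporter gene Slc2a1 by 0.14 (SE 0.12), Hbb-y by −0.02 (SE 0.53) and Xist by 0.15 (SE 1.25). Each SE rests on a variance per gene shared by the arrays of both days, and for Hbb-y and Xist it mostly carries the E15.5 spread. Hbb-y ran from 13.96 to 14.26 at E13.5 and from 11.46 to 14.10 at E15.5. Xist ran from 9.90 to 12.03 at E13.5 and from 6.13 to 12.48 at E15.5. Limma called 0 of 11826 genes at adjusted p < 0.05, in each alternative tried as well. It gave 127 genes with an unadjusted value below 0.05, 33 higher and 94 lower in diabetes hearts, where chance alone gives 591. Fitted to the E13.5 arrays alone, without the E15.5 spread in the variance, it gave 174. Simulated 2-fold changes were recovered in 97% of genes at this array number and 1.5-fold changes in 72.5%. The simulated genes varied independently, without the structure of these pools. Of the measured genes, 9 differed over 1.5-fold and 2 over 2-fold with none called, so changes of that size are not excluded. The median 95% interval of a gene reached 1.16-fold to either side.

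The genes with the smallest p-values at E13.5 had small differences, each with an adjusted p of 1. On the higher side were Napb, a gene of vesicle fusion, at +0.26 (SE 0.08), the secreted Wnt antagonist Sfrp5 at +0.33 (SE 0.10), Cog5 of the Golgi at +0.30 (SE 0.10), the DNA repair gene Abraxas1 at +0.21 (SE 0.07) and Dtd2 at +0.27 (SE 0.09). Another bright probe set of Napb gave −0.04. On the lower side were Reps2 at −0.50 (SE 0.12), Fam13c at −0.35 (SE 0.08), Nat8f1 at −0.31 (SE 0.08), the calmodulin kinase gene Camk2b at −0.36 (SE 0.10) and the growth factor gene Gdf9 at −0.32 (SE 0.09). In all 10 the 3 arrays of one group lay above the 3 of the other. Such a separation was found for 543 genes, or 4.59%, against the 10% that chance gives.

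Among the gene lists, 2 passed the preset camera test at E13.5. Markers of epithelium from lung, thymus and other tissue near the heart were higher in diabetes hearts, with all 8 measured members above 0 and a median of +0.23 (adjusted p = 0.021; adjusted p = 0.98 with an estimated correlation). Foxa2, an endoderm transcription factor gene, was at +0.42 (SE 0.23) and Epcam, an epithelial adhesion gene, at +0.64 (SE 0.78). Epcam was at 7.13, 5.32 and 5.14 in control replicates 1 to 3 and at 6.60, 7.08 and 5.84 in diabetes replicates 1 to 3, and differed by +1.28 without control replicate 1. Epicardial markers were lower, with 11 of 14 members below 0 and a median of −0.16 (adjusted p = 0.040; adjusted p = 0.98 with an estimated correlation). Among them the epicardial transcription factor genes Tbx18 and Wt1 were at −0.19 and −0.18 and the retinoic acid synthesis gene Aldh1a2 at −0.21 (SE 0.10 to 0.15). No member of either list was called, over all genes or adjusted over the list alone. The epithelium call ended without control replicate 2 (adjusted p = 0.345), control replicate 3 (0.398), diabetes replicate 1 (0.167) or diabetes replicate 2 (0.112). The epicardial call ended without E13.5 control replicate 3 (0.398), E13.5 diabetes replicates 1 (0.556) and 3 (0.243), and E15.5 control and diabetes replicates 1 (0.054 and 0.053), and after quantile normalization both calls ended at 0.053. The endothelial list had 15 of 17 members above 0 (median +0.05, adjusted p = 0.134) and the hypoxia list 15 of 21 (median +0.05, adjusted p = 0.125). Among fibroblast markers, 10 of 12 were below 0 (median −0.06, adjusted p = 0.459). The hypoxia list was called without E13.5 control replicate 2 (0.015), E13.5 diabetes replicate 1 (0.011) or 2 (0.020) or E15.5 diabetes replicate 2 (0.039), and the endothelial and fibroblast lists without E13.5 diabetes replicate 2 (0.010 each).

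The second comparison put the same question at E15.5. Differences were wider than at E13.5, and again no gene passed the test. Tent5c, a gene for a poly(A) polymerase, was at 9.36 ± 0.12 in control and 10.43 ± 0.29 in diabetes hearts (SD, n = 3 arrays each), a 2.10-fold difference with SE 0.18 on the log2 scale. Ifitm3, an interferon-induced membrane protein gene, was at 8.35 ± 0.07 and 9.51 ± 0.40, a 2.23-fold difference with SE 0.20. Fam167b, the imprinted gene Magel2 and Ric1 were higher by 0.53 (SE 0.09), 0.48 (SE 0.09) and 0.34 (SE 0.07). On the lower side, Kalrn was at 7.87 ± 0.10 in control and 7.22 ± 0.19 in diabetes hearts (−0.65, SE 0.09). Another bright probe set of Kalrn gave 0.03. Lbh, a regulator of transcription in limb bud and heart, was at 9.98 ± 0.20 and 9.44 ± 0.07 (−0.54, SE 0.09). Chid1, Haus8 of the mitotic spindle and Rgs9bp were lower by 0.42 (SE 0.07), 0.40 (SE 0.07) and 0.55 (SE 0.11). In each of these 10 genes the groups did not overlap. Their adjusted p lay between 0.173 and 0.302.

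**Figure D2:**
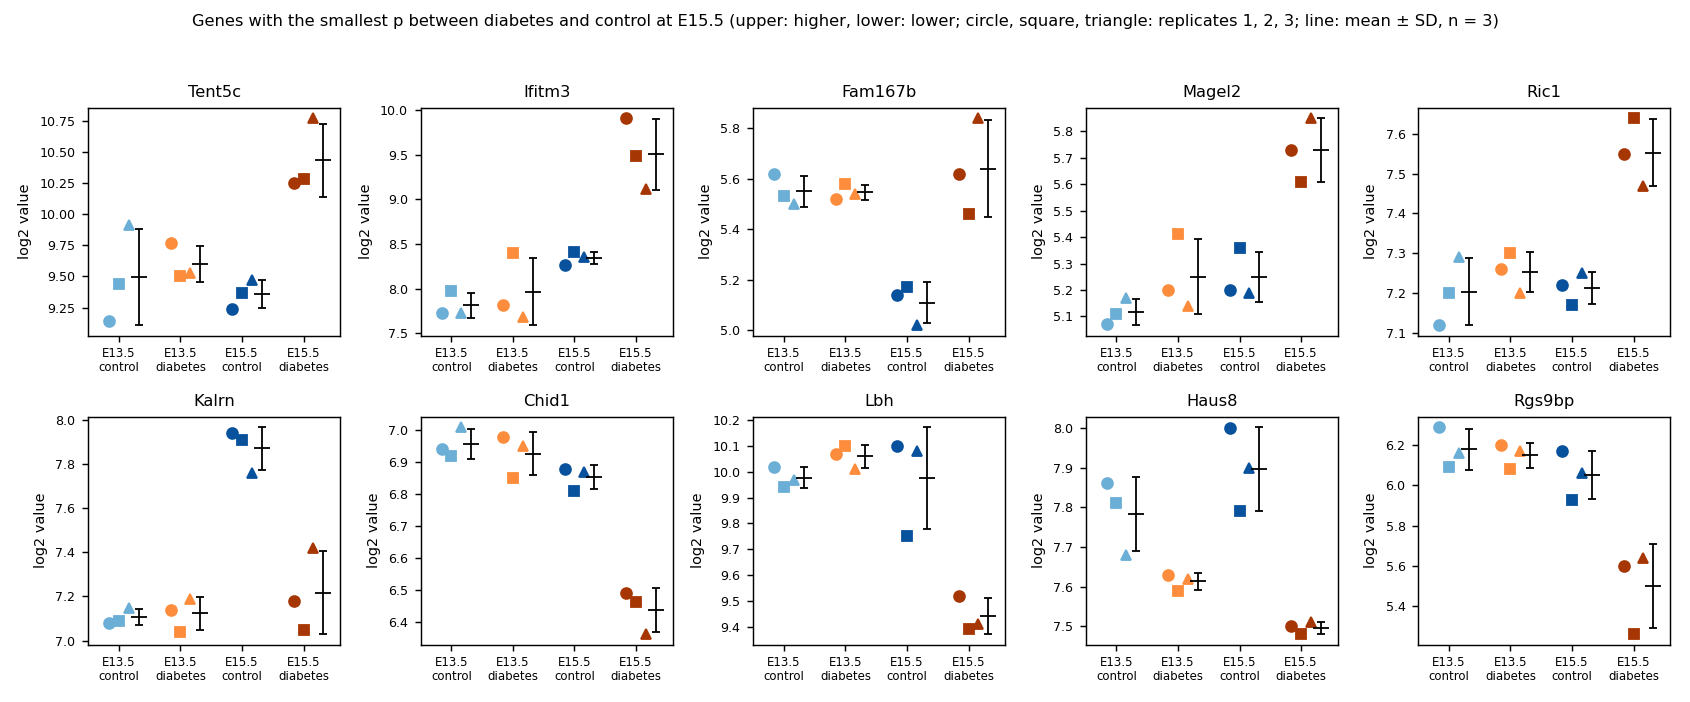
Log2 intensity in each array of the 10 genes with the smallest p at E15.5, 5 higher in diabetes hearts (upper panels) and 5 lower (lower panels), in the 4 groups (points, 1 per array; lines, mean ± SD of 3 arrays). Tent5c lies at 9.36 in control and 10.43 in diabetes hearts on average, and Kalrn at 7.87 and 7.22.

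The cardiac reference genes at E15.5 differed by no more than 0.15 in either direction: Nppa by 0.06, Myh6 by 0.09, Myh7 by −0.08, Nkx2-5 by −0.04, Gata4 by −0.13, Slc2a1 by 0.05 and Vegfa by 0.15 (SE 0.09 to 0.23). Hbb-y differed by −0.25 (SE 0.53) and Xist by −1.43 (SE 1.25), the latter with diabetes replicates 2 and 3 at its extremes. The sign for Hbb-y rests on diabetes replicate 2: the diabetes replicates 1 to 3 were at 13.85, 11.46 and 14.10 and the control replicates at 13.06, 14.08 and 13.03. Limma called 0 genes at adjusted p < 0.05 and gave 998 with an unadjusted value below 0.05, 398 higher and 600 lower in diabetes hearts, against 591 by chance. The groups did not overlap for 1457 genes, or 12.3%, against 10% by chance. Simulated 2-fold changes were recovered in 96% of genes and 1.5-fold changes in 79%, while 99 genes differed over 1.5-fold and 30 over 2-fold. The count became 1 without E13.5 diabetes replicate 3, 1 without E15.5 control replicate 2 (Lbh, adjusted p = 0.029), and 2 without E15.5 diabetes replicate 3 (among them Kalrn, adjusted p = 0.016). Leaving out control replicate 2 and diabetes replicate 2 together, the E15.5 pools apart in globins, a choice made after seeing the data, gave 48 called genes, 24 in each direction. The arrays then left were parted by embryonic globins as well as by condition (9.84 and 9.74 in control, 11.08 and 11.91 in diabetes hearts).

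At E15.5 the preset camera test called 4 lists. Hypoxia genes were higher in diabetes hearts, with 18 of 21 members above 0 and a median of +0.15 (adjusted p = 0.023; adjusted p = 0.82 with an estimated correlation). The Myc antagonist gene Mxi1 was at +0.28 (SE 0.11), the glycolysis regulator gene Pfkfb3 at +0.26 (SE 0.14) and the histone demethylase gene Kdm3a at +0.17 (SE 0.09), and another bright probe set of Mxi1 gave −0.20. Diabetes replicate 2 held the high values, with a list mean of 8.96 against 8.31 to 8.64 in the other arrays, and without it the adjusted p was 0.855. Cell cycle genes were lower, with 28 of 35 members below 0 and a median of −0.08 (adjusted p = 0.023; adjusted p = 0.83 with an estimated correlation). The mitotic genes Bub1 and Birc5 were both at −0.18 and the cyclin-dependent kinase gene Cdk1 at −0.19 (SE 0.06 to 0.08), and without diabetes replicate 2 the adjusted p was 0.698. Epicardial markers were higher, with 11 of 14 members above 0 and a median of +0.16 (adjusted p = 0.023; adjusted p = 0.77 with an estimated correlation). Gpm6a was at +0.37 (SE 0.11), Wt1 at +0.27 (SE 0.10) and the keratin gene Krt8 at +1.25 (SE 0.64), with 10.74 in diabetes replicate 1, and the call ended without control replicate 3 (0.133) or diabetes replicate 3 (0.211). The list mean was 8.04, 7.80 and 8.03 in diabetes replicates 1 to 3 and 7.82, 7.82 and 7.56 in control replicates 1 to 3. The mean of the epithelium markers was 5.89, 4.89 and 5.45 in these diabetes replicates and 5.36, 5.42 and 4.58 in the control replicates, so both lists were lowest in the same array of each group. Over all arrays of both days, deviations of the epicardial and epithelium means from their group means correlated at r = 0.73. Notch pathway genes were higher as well, with 13 of 16 members above 0 and a median of +0.12 (adjusted p = 0.035; adjusted p = 0.77 with an estimated correlation). Notch3 was at +0.27 (SE 0.11) and Maml1 at +0.26 (SE 0.14), and the call ended without control replicate 3 (0.052) or diabetes replicate 1 (0.291). The number of lists called was 12 without control replicate 2, 7 without diabetes replicate 1 and 10 without diabetes replicate 2. With the mean of all probe sets of a gene in place of the brightest, the epicardial call alone remained (0.046).

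Several further lists had an adjusted p of 0.064 to 0.167 at E15.5 by the preset camera test and were not called. With an estimated correlation their adjusted p was 0.77 to 0.88, so only the preset test put any of them near the threshold. Ventricular markers had a median of −0.07 (adjusted p = 0.111), and 2 of the 10 were lower when adjusted over the list alone, Lbh and the transcriptional co-regulator gene Cited1 at −0.39 (SE 0.11). The mixed form of fry called this list (adjusted p = 7.0e-04), its only call in a diabetes contrast. Fry for a change in 1 direction did not (adjusted p = 0.75). Genes of the endoplasmic reticulum stress response had a median of −0.11 (adjusted p = 0.064), with the protein folding genes Sdf2l1 at −0.76 (SE 0.22), Pdia6 at −0.44 (SE 0.13) and Calr at −0.37 (SE 0.13). Red cell markers had a median of +0.16 (adjusted p = 0.064), and 1 of the 10, the heme synthesis gene Alas2 at +0.79 (SE 0.21), was higher when adjusted over the list alone. Slc4a1, the red cell anion exchanger gene, was at +0.65 (SE 0.25). Skeletal muscle markers had a median of +0.39 (adjusted p = 0.064), with Myh3 at +1.40 (SE 0.83) and diabetes replicate 3 far above the rest. Glycolysis genes had a median of −0.10 (adjusted p = 0.111), with Pfkl at −0.24 (SE 0.07). Antioxidant genes had a median of +0.06 (adjusted p = 0.111), with Gpx1 at +0.30 (SE 0.13) and Hmox1 at +0.22 (SE 0.11). Leukocyte markers had a median of +0.05 (adjusted p = 0.167), with Ptprc at +1.34 (SE 0.59). Ptprc was at 8.61, 5.35 and 7.10 in diabetes replicates 1 to 3 and at 5.25 to 6.14 in the control replicates. The fits without single arrays used the preset correlation alone, while the estimated one was 0.56 for leukocyte, 0.50 for red cell and 0.46 for glycolysis genes. Leaving out single arrays turned each of these lists but the antioxidant list into a called one. Without E15.5 diabetes replicate 2 this held for the ventricular (adjusted p = 0.014), red cell (6.2e-05), skeletal muscle (0.0059), glycolysis (1.3e-04) and leukocyte lists (4.0e-06). Without E15.5 control replicate 2 it held for the red cell (0.0011), skeletal muscle (0.017) and leukocyte lists (0.0087). The endoplasmic reticulum stress list was called without E15.5 control replicate 1 (0.027) or 3 (0.0035) or E15.5 diabetes replicate 1 (0.0024). The ventricular list was also called without E15.5 control replicate 1 (0.032), the skeletal muscle list without E15.5 diabetes replicate 1 (0.019) and the red cell list without E13.5 control replicate 3 (0.046).

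**Figure D3:**
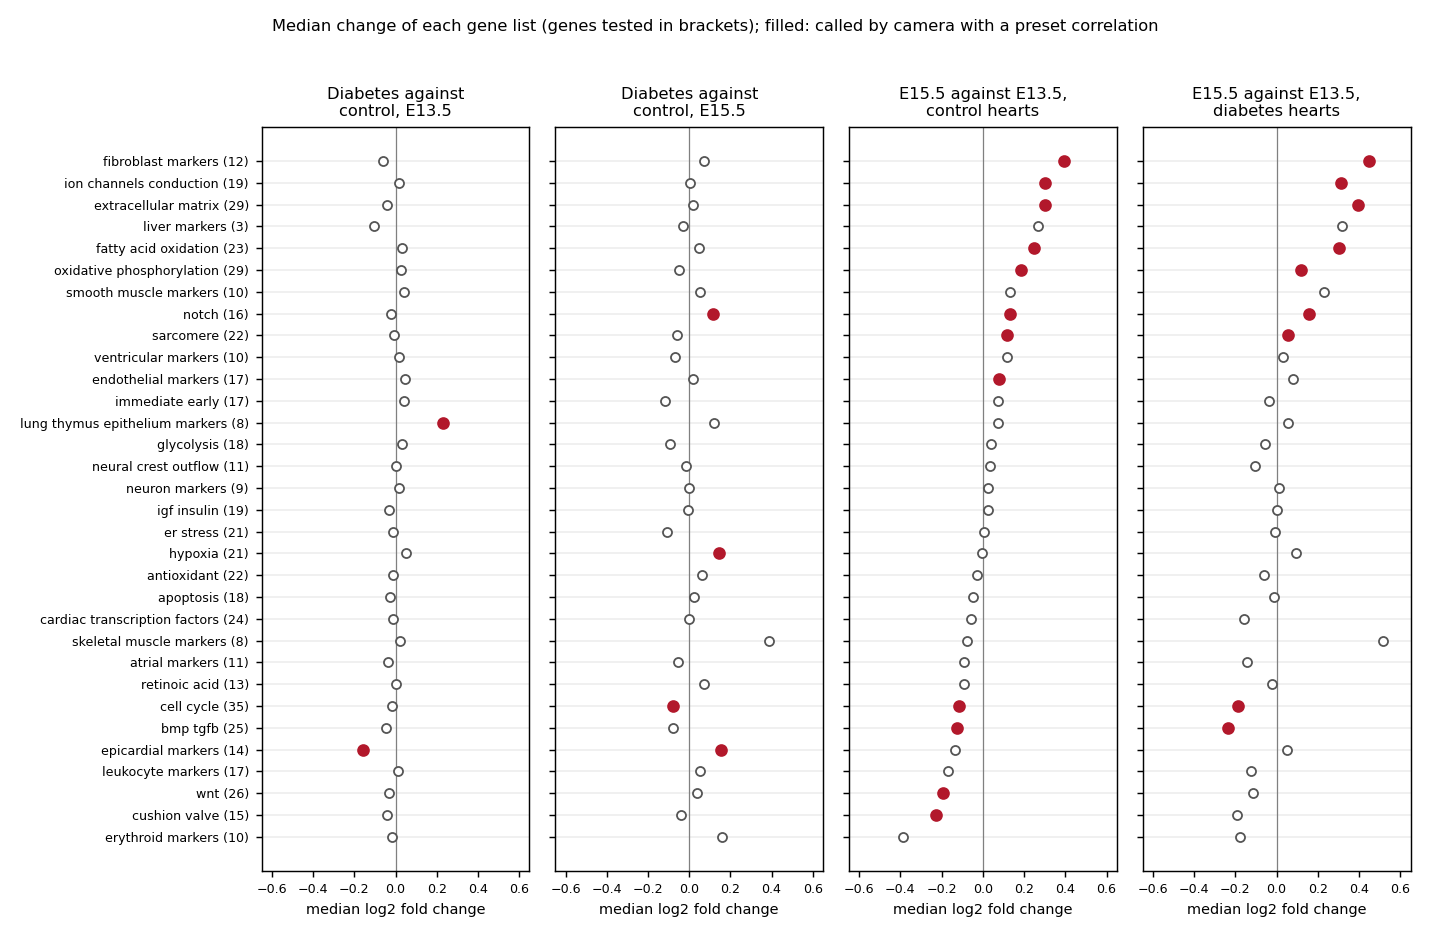
Median log2 difference of each gene list (points; filled where the preset camera test called the list, adjusted p < 0.05) in the diabetes comparisons at E13.5 and E15.5 and the age comparisons in control and diabetes hearts. The epicardial list lies at −0.16 at E13.5 and at +0.16 at E15.5.

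Whether the difference between diabetes and control hearts changed from E13.5 to E15.5 was tested directly. Epicardial markers had a more positive diabetes effect at E15.5 than at E13.5, in 13 of 14 members and with a median of +0.26 (adjusted p = 0.0012; adjusted p = 0.84 with an estimated correlation). Gpm6a was at +0.56 (SE 0.16), Wt1 at +0.45 (SE 0.14) and Bnc1, a gene of mesothelium, at +0.42 (SE 0.24). This call held without each of the 12 arrays in turn, with an adjusted p of 5.8e-05 to 0.041. Of the ventricular markers, Lbh at −0.62 (SE 0.13) and Cited1 at −0.56 (SE 0.15) were lower when adjusted over the list alone (list median −0.08, adjusted p = 0.080). Notch genes had a median of +0.11 (adjusted p = 0.089), with Notch3 at +0.41 (SE 0.16), and glycolysis genes one of −0.12 (adjusted p = 0.080), with Pfkl at −0.21 (SE 0.10). Without E15.5 diabetes replicate 2 the ventricular (0.0055), Notch (0.039) and glycolysis lists (9.1e-05) were called, as they were without E13.5 diabetes replicate 2 (0.017, 0.031 and 0.011). The ventricular and glycolysis lists were also called without E13.5 control replicate 2 (0.017 and 0.024) or E15.5 control replicate 2 (0.046 and 0.032), the ventricular list without E15.5 control replicate 1 (0.030) and the glycolysis list without E13.5 control replicate 1 (0.046). Single genes with the smallest p were Fam167b (+0.53, SE 0.13), Procr (+0.49, SE 0.12), Gtf3c2 (+0.40, SE 0.10), B3gnt9 (+0.58, SE 0.15) and Fam13c (+0.45, SE 0.12) on the positive side. On the negative side were Abraxas1 (−0.54, SE 0.10), Kalrn (−0.67, SE 0.13), Lmf1 (−0.56, SE 0.12), Lbh and B3gnt5 (−1.21, SE 0.26). None passed the test (adjusted p = 0.997 each), and other bright probe sets of Kalrn and Gtf3c2 gave 0.06 and −0.02. The reference genes ran from −0.24 for Hbb-y (SE 0.75) to +0.13 for Myh6 (SE 0.15), apart from Xist at −1.58 (SE 1.76). Limma called 0 genes and gave 517 with an unadjusted value below 0.05, 262 positive and 255 negative. Without E13.5 diabetes replicate 3, 1 gene was called, B3gnt5 (adjusted p = 0.042). Simulated differences of 2-fold were recovered in 89% of genes and those of 1.5-fold in 40%.

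Across genes, the diabetes effects at the 2 days, which share no arrays, correlated at r = 0.05 (Spearman rho = −0.01, jackknife SE of r over arrays 0.19), and 48.3% of genes had the same sign. Genes are not independent replicates, and no p is given. The sign of r turned without E13.5 control replicate 1 (−0.01) and E13.5 diabetes replicate 2 (−0.09), with array weights (−0.02) and with a filter at the 75th percentile (−0.05).

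The third comparison described the change with age in control hearts, E15.5 against E13.5. By the preset test, lists of fat metabolism, matrix and muscle genes were called upward and the list of the endocardial cushions downward, and no list was called with an estimated correlation (smallest adjusted p = 0.13). Abca8a, a lipid transporter gene, rose 4.25-fold, from 5.92 ± 0.16 to 8.01 ± 0.59 (SD, n = 3 arrays each), and Ptgds, the prostaglandin D2 synthase gene, rose 4.25-fold, from 7.35 ± 0.04 to 9.44 ± 0.60. Ckm, the muscle creatine kinase gene, rose 4.11-fold. Scgb3a2, a secretoglobin gene known from airway epithelium, rose from 5.75 ± 0.29 to 9.78 ± 1.87, or 16.3-fold. For Scgb3a2 the log2 difference of 4.03 was 2.99 without E15.5 control replicate 1 (adjusted p = 0.052) and 4.80 without E15.5 control replicate 3. The epithelium markers were not called as a list (median +0.07, preset camera adjusted p = 0.52). Whether airway tissue from beside the heart carried the Scgb3a2 rise was not tested. Hapln1, which links hyaluronan in the cushions, fell 3.30-fold, from 7.50 ± 0.11 to 5.78 ± 0.45. Pdzk1ip1 fell 3.52-fold and the carbonic anhydrase gene Car3 2.74-fold. The matrix protein gene Abi3bp rose by 2.05 (SE 0.41), C1ql3 fell by 1.78 (SE 0.20) and the membrane curvature gene Amph fell by 1.36 (SE 0.27). In these 3 the dimmer group had a mean no higher than the filter at 5.04, so no fold is given. Limma called 131 genes at adjusted p < 0.05, 65 higher and 66 lower at E15.5, and the adjusted p of these 10 lay between 0.00495 and 0.037. The groups did not overlap for 24.9% of all genes, against 10% by chance. Nppa, Myh6, Myh7, Nkx2-5, Gata4 and Vegfa differed by −0.15 to +0.30 with age and were not called. Neither were Slc2a1 (−0.33, SE 0.12), Hbb-y (−0.71, SE 0.53) or Xist (+0.50, SE 1.25). Slc2a1 was called without E15.5 control replicate 2 (adjusted p = 0.036).

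As groups, fatty acid oxidation genes rose with age in control hearts, with all 23 members above 0, 3 of them called and 9 when adjusted over the list alone, and a median of +0.25 (adjusted p = 1.4e-11; adjusted p = 0.41 with an estimated correlation). The lipid regulator gene Ppara rose by 1.46 (SE 0.24) from a mean of 4.86, below the filter, the fatty acid transporter gene Cd36 by 0.95 (SE 0.18) and Pdk4, which limits glucose oxidation, by 0.58 (SE 0.11). Oxidative phosphorylation genes rose as a list, with a median of +0.18 and 29 of 29 estimates above 0, none called by itself over all genes and 1 adjusted over the list alone (adjusted p = 1.5e-10; adjusted p = 0.41 with an estimated correlation). Extracellular matrix genes rose by a median of 0.30, with 4 members called and, adjusted over the list alone, 15 higher and 2 lower (adjusted p = 1.1e-10; adjusted p = 0.31 with an estimated correlation). Col6a3 rose by 0.96 (SE 0.17), Col6a1 by 0.90 (SE 0.17), the basement membrane gene Nid1 by 0.43 (SE 0.09) and Dcn by 0.78 (SE 0.17). Fibroblast markers rose by a median of 0.40, with 2 of 12 called and 7 over the list alone, Dpt among them at +1.82 (SE 0.30; list adjusted p = 3.0e-06; adjusted p = 0.31 with an estimated correlation). Ion channel and conduction genes rose by a median of 0.30 with Casq2, a calcium store gene, at +1.09 (SE 0.17), 1 of 19 called and 2 over the list alone (adjusted p = 4.1e-05; adjusted p = 0.41 with an estimated correlation). Sarcomere genes rose by a median of 0.12 with Ttn at +0.59 (SE 0.12), 1 of 22 called and 2 over the list alone (adjusted p = 5.2e-05; adjusted p = 0.59 with an estimated correlation). Notch genes (median +0.13, 0 of 16 called, adjusted p = 0.018; adjusted p = 0.41 with an estimated correlation) and endothelial markers (median +0.08, adjusted p = 0.033; adjusted p = 0.66 with an estimated correlation) also rose as lists. Of the endothelial markers 1 of 17 was called, the tight junction gene Cldn5 at +0.88 (SE 0.16), and over the list alone 3 were higher and 1 lower.

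Downward in control hearts were cell cycle genes, with a median of −0.12, 32 of 35 below 0 and none called (adjusted p = 3.1e-04; adjusted p = 0.59 with an estimated correlation). Genes of BMP and TGF-beta signalling fell by a median of 0.12, with Bmp4 called at −0.74 (SE 0.14) and 6 of 25 over the list alone (adjusted p = 0.0014; adjusted p = 0.13 with an estimated correlation). Wnt genes fell by a median of 0.19 with 0 of 26 called and 6 over the list alone (adjusted p = 0.0077; adjusted p = 0.31 with an estimated correlation). Rspo3 was at −0.80 (SE 0.21) and Sfrp2 at −0.45 (SE 0.12), and both were called without E15.5 control replicate 2 (0.020 and 0.034). Cushion and valve genes fell by a median of 0.23, with Hapln1 and the mesenchymal transcription factor gene Twist1 (−1.0, SE 0.18) called and, over the list alone, 5 of 15 lower and 2 higher (adjusted p = 0.044; adjusted p = 0.31 with an estimated correlation). The cushion call ended, with an adjusted p of 0.051 to 0.085, without E13.5 control replicates 1 and 3, E13.5 diabetes replicate 2, E15.5 control replicates 1 and 3 or E15.5 diabetes replicates 1 and 2. The endothelial call ended without E13.5 control replicate 3 (0.060). Among red cell markers Hbb-bh1 was at −3.56 (SE 0.87) and Hba-x at −3.12 (SE 0.83), and the list was not called (median −0.39, adjusted p = 0.051). Without E15.5 control replicate 2 Hbb-bh1 was at −4.26 and called (adjusted p = 0.037), and Hba-x was at −3.75. The red cell list was called without E13.5 control replicate 1 (0.0035), E15.5 control replicate 2 (0.0018) or E15.5 diabetes replicate 2 (0.0088) or 3 (0.033). Adjusted over the list alone, 3 of its 10 members were lower and 1 higher.

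The count in control hearts depended on the fit and on single pools. It was 2324 with array weights, 360 with the arrays compared alone and 3 with the erythroid mean as a covariate, a choice made after seeing the data. The tested red cell markers themselves had a mean difference of −0.845 with age in control hearts. This covariate therefore overlaps with the day, and its count does not show that blood content explains the age changes. The count was 11 without E13.5 control replicate 1, 21 without replicate 2 and 9 without replicate 3, and 11 without E15.5 control replicate 1 or 3. It was 290 without E15.5 control replicate 2 and 362 without E15.5 diabetes replicate 2. Of the 10 named genes, Ptgds, C1ql3 and Hapln1 stayed called without any one control array (highest adjusted p = 0.048). The other 7 lost the call in 3 to 6 of those 6 fits, with a highest adjusted p of 0.061 for Pdzk1ip1 and 0.18 for Amph.

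The fourth comparison described the change with age in diabetes hearts. Scgb3a2 rose from 5.69 ± 0.51 to 11.04 ± 0.89 (SD, n = 3 arrays each), or 40.8-fold. It is known from airway epithelium, and whether tissue from beside the heart carried this rise was not tested. The carbonyl reductase gene Cbr2 rose 6.65-fold, Myom2 of the sarcomere's M-band 5.84-fold and Abca8a 5.18-fold. Hbb-bh1 fell 12.2-fold, from 11.77 ± 0.56 to 8.16 ± 2.04, with E15.5 diabetes replicate 2 at 5.88. For Hbb-bh1 the log2 difference of −3.61 was −2.47 without that array (adjusted p = 0.054) and −4.45 without E15.5 diabetes replicate 3. Hapln1 fell 4.50-fold, Pdzk1ip1 2.88-fold and the cardiac transcription factor gene Gata5 2.76-fold. Agtr2, the angiotensin II type 2 receptor gene, rose by 3.32 (SE 0.61) from a mean of 4.63 and Nipal4 fell by 1.72 (SE 0.41) to a mean of 4.17, both below the filter, so no fold is given. For Agtr2 the log2 difference was 2.68 without E13.5 diabetes replicate 1 and 4.15 without E13.5 diabetes replicate 2. Limma called 1030 genes, 454 higher and 576 lower at E15.5, and the adjusted p of these 10 lay between 7.2e-04 and 0.028. The groups did not overlap for 27.2% of all genes, against 10% by chance. Among the reference genes Slc2a1 fell by 0.43 (SE 0.12, adjusted p = 0.045), and Nppa, Myh6, Myh7 and Vegfa differed by −0.06 to +0.32 without being called. Nkx2-5 was at −0.30 (adjusted p = 0.059), Gata4 at −0.22 (adjusted p = 0.12), Hbb-y at −0.94 (SE 0.53) and Xist at −1.08 (SE 1.25). For Hbb-y and Xist these values rest largely on E15.5 diabetes replicate 2 (11.46 and 6.13). E15.5 diabetes replicates 1 and 3 were at 13.85 and 14.10 for Hbb-y and at 11.77 and 12.48 for Xist. Nkx2-5 was called without E15.5 diabetes replicate 3 (adjusted p = 0.025) and Gata4 without E15.5 diabetes replicate 2 (0.048).

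As groups, extracellular matrix genes rose in diabetes hearts by a median of 0.40, with 11 of 29 up and 1 down and, adjusted over the list alone, 17 up and 2 down (adjusted p = 4.0e-08; adjusted p = 0.45 with an estimated correlation). Col6a3 rose by 1.19 (SE 0.17), Col6a1 by 1.04 (SE 0.17) and Col1a1 by 1.03 (SE 0.18). Fatty acid oxidation genes rose by a median of 0.30, with 7 of 23 called and 11 over the list alone (adjusted p = 4.0e-08; adjusted p = 0.64 with an estimated correlation), among them Cd36 at +1.10 (SE 0.18), Pdk4 at +0.89 (SE 0.11) and Acaa2 at +0.75 (SE 0.15). Fibroblast markers rose by a median of 0.45, with 7 of 12 called both ways of adjusting and Dpt at +2.01 (SE 0.30; list adjusted p = 1.4e-05; adjusted p = 0.45 with an estimated correlation). Notch genes rose by a median of 0.16 with 4 of 16 called and 5 over the list alone (adjusted p = 6.4e-04; adjusted p = 0.45 with an estimated correlation), Nrarp at +0.83 (SE 0.15), Notch3 at +0.69 (SE 0.11) and Heyl at +0.51 (SE 0.11). Oxidative phosphorylation genes rose by a median of 0.12, with 3 of 29 called both ways and Cycs at +0.34 (SE 0.08; list adjusted p = 4.5e-04; adjusted p = 0.83 with an estimated correlation). Ion channel and conduction genes rose by a median of 0.31, with 3 of 19 called, Casq2 at +0.99 (SE 0.17) and Sln at +1.58 (SE 0.31; list adjusted p = 0.0051; adjusted p = 0.83 with an estimated correlation). Over that list alone 7 were higher and 2 lower. Sarcomere genes rose by a median of 0.06, with 2 of 22 called, Ldb3 at +0.41 (SE 0.10) and Tnnt2 at +0.26 (SE 0.07), and 4 over the list alone (adjusted p = 0.047; adjusted p = 0.83 with an estimated correlation).

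Cell cycle genes fell in diabetes hearts by a median of 0.19, with 6 of 35 called and 11 over the list alone (adjusted p = 1.0e-05; adjusted p = 0.64 with an estimated correlation), among them Bub1 at −0.34 (SE 0.06) and Cdk4 at −0.44 (SE 0.09). Genes of BMP and TGF-beta signalling fell by a median of 0.23, with 7 of 25 lower and 1 higher, and 9 lower and 1 higher over the list alone (adjusted p = 0.0086; adjusted p = 0.30 with an estimated correlation). Bmp4 fell by 0.76 (SE 0.14), Tgfb2 by 0.62 (SE 0.12) and Bmp7 by 0.45 (SE 0.07). Cushion and valve genes missed the threshold of camera as a list (median −0.19, adjusted p = 0.058) and passed that of fry (adjusted p = 0.0065), while 5 of 15 fell and 1 rose, and over the list alone 6 fell and 3 rose. Camera called this list without E13.5 diabetes replicate 3 (0.014) or E15.5 control replicate 2 (0.043) or 3 (0.044). The matrix gene Vcan was down by 0.60 (SE 0.09) at its brightest probe set, Twist1 by 0.95 (SE 0.18) and Msx2 by 0.53 (SE 0.10). Wnt genes (median −0.12, adjusted p = 0.30, 5 of 26 fell) and endothelial markers (median +0.08, adjusted p = 0.22, 1 of 17 rose) were not called as lists. Red cell markers split, with Alas2 up by 1.09 (SE 0.21) and Fech up by 0.72 (SE 0.18), and Ermap down by 0.90 (SE 0.21) (list median −0.18, adjusted p = 0.70). The oxidative phosphorylation call ended without E15.5 diabetes replicate 2 (0.112) and the ion channel call without E13.5 diabetes replicate 2 (0.103). The sarcomere call ended without E13.5 control replicates 1 (0.050) and 2 (0.053), E13.5 diabetes replicate 2 (0.370) or E15.5 diabetes replicate 2 (0.434). The count of genes was 189 with the arrays compared alone, 477 with the erythroid mean as a covariate, a choice made after seeing the data, and 347 without E13.5 diabetes replicate 1, 626 without E13.5 diabetes replicate 3 and 579 without E15.5 diabetes replicate 2. That covariate overlaps with the day here as well, since the tested red cell markers had a mean difference of −0.670 with age. The highest adjusted p among fits without 1 diabetes array was 0.062 for Cbr2, 0.079 for Hbb-bh1, 0.087 for Nipal4 and 0.12 for Slc2a1. The other 7 of the 10 named genes stayed called in each of these fits.

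The age effects in control and diabetes hearts, which share no arrays, correlated across genes at r = 0.77 (Spearman rho = 0.64), with a slope of 0.96 for diabetes on control hearts. Genes are not independent replicates. The number called in both was 60 higher, where independent calls would give 2.5, and 55 lower, where they would give 3.2, and none was called in opposite directions. The calls are not fully independent, since both contrasts use the same variance per gene, which can by itself raise the overlap. Of the 131 genes called in control hearts, 130 had the same sign in diabetes hearts, as had 992 of the 1030 in the other direction. The counts 131 and 1030 do not show a difference between the groups, since the test of that difference is the interaction, for which limma called 0 genes (517 at an unadjusted value below 0.05). Both counts rest on a variance per gene shared by all groups, although diabetes pools varied more. The median SD of a gene was 0.09 and 0.10 in control and 0.11 and 0.12 in diabetes hearts at E13.5 and E15.5. The order of the counts turned with the arrays compared alone (360 and 189), with array weights (2324 and 1468) and without E15.5 control replicate 2 and diabetes replicate 2 (852 and 754).

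**Figure D4:**
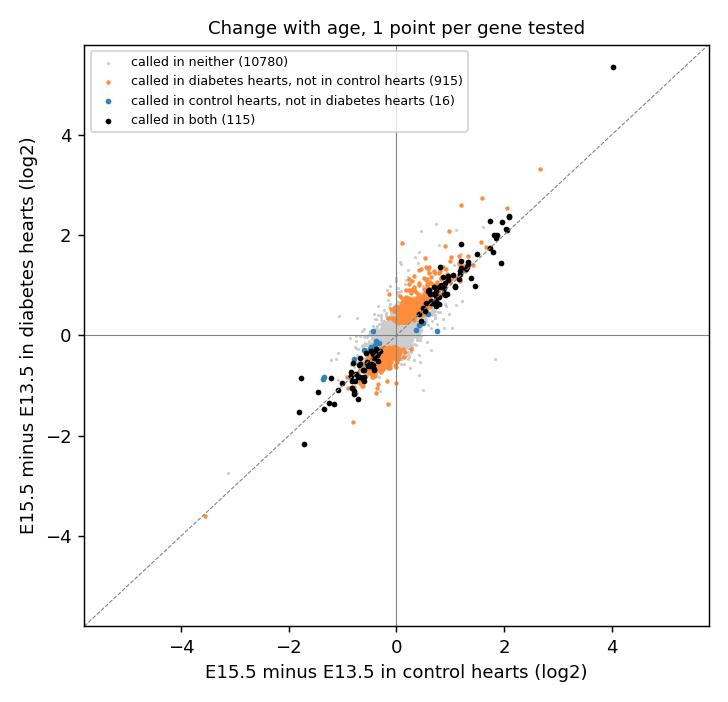
Log2 difference between E15.5 and E13.5 in control hearts (horizontal) against diabetes hearts (vertical), 1 point per gene tested, coloured by call. The 115 genes called in both lie near the diagonal (dashed), 915 were called in diabetes hearts and not in control hearts, and 16 the other way round.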

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

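The permutation and covariate tests of the list mean in this part were chosen after the result was seen. A single result met a rule for a closer look: the diabetes effect on the epicardial markers differed between E13.5 and E15.5 by the preset camera test of the interaction (list adjusted p = 0.0012). Fry did not call this list (adjusted p = 0.93). The mean of the 14 markers was 7.82, 7.76 and 7.90 in E13.5 control replicates 1 to 3 and 7.61, 8.01 and 7.57 in diabetes replicates 1 to 3. At E15.5 it was 7.82, 7.82 and 7.56 in control and 8.04, 7.80 and 8.03 in diabetes replicates. By gene, the difference between the effects was +0.45 for Wt1, +0.56 for Gpm6a, +0.42 for Bnc1, +0.43 for Lrrn4, +0.33 for Aldh1a2 and −0.10 for Tcf21. The keratin gene Krt8 had the largest, +1.01 (limma, unadjusted p = 0.29). Adjusted p was 5.8e-05 to 0.041 without each array in turn and 0.84 with an estimated correlation between the genes.

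The preset test treats the 14 genes as nearly independent, and the groups overlap at both days. Relabelling the arrays within the days gave an interaction of the list mean as large as the real 0.32 (SE 0.19) in 26 of 200 relabellings (exact permutation test, two-sided p = 0.13), so chance variation between pools may account for it. Whether epithelium from beside the heart in some pools was the whole source is not settled. With the mean of those markers as a covariate the interaction was 0.30 (SE 0.14), above the midpoint between 0 and its former value by slightly more than its SE. The epithelium markers differed by similar amounts at both days (diabetes minus control 0.23 at E13.5 and 0.29 at E15.5). The covariate could therefore change the interaction little, and its SE is wide. A part from such epithelium stays open as well. At E15.5 both lists were lowest in the same array of each group, and over the 12 arrays their deviations from the group means correlated at r = 0.73. A change between the days in the epicardium of hearts of malformed embryos, which the design allows, stays open and was not tested apart from these values.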

How the results depend on the processing

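The erythroid covariate and the fits without pairs of arrays were chosen after seeing the data. That covariate itself differed between the days, so it overlaps with the age contrasts. The count of genes called at E13.5 was 0 in every alternative, and the median of all genes moved by less than 0.1 under either rescaling. Of the 70 gene results called, 69 stayed called after quantile normalization and 54 with a replicate block, as did 37 of 57 values at other bright probe sets, 4 of 27 at dim probe sets and 245 of 420 without 1 array. Of the 28 list results called, 27 stayed called after median centring, 25 after quantile normalization, 22 with the mean of all probe sets, 18 with the erythroid covariate, 20 without E15.5 diabetes 2 and 3 (1 turned) and 307 of 336 values without 1 array. Of the results not called, signs turned in 30 of 77 values at dim probe sets, 23 of 147 at bright ones and 38 of 1350 without 1 array. Signals near background limit the dim probe sets.

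Genes called at E15.5 (0) became 4 with array weights, 1 with the Y-linked mean and 1 with the erythroid mean as a covariate, 48 without E15.5 control 2 and diabetes 2, 77 without E15.5 diabetes 2 and 3 (74 higher, with the lone diabetes array assumed to vary like the other groups), 56 at unadjusted p < 0.05 with a 1.5-fold change in limma's fit, which are not permutation values, and 0 to 2 without 1 array. The interaction (0) gave 25 without E15.5 diabetes 2 and 3, 51 by the unadjusted rule and 0 to 1 without 1 array. Control hearts with age (131) gave 2324 with array weights, 3 with the erythroid covariate, 852 and 327 without the pairs, 360 with the arrays compared alone, 398 at an adjusted p below 0.10, 255 by the unadjusted rule and 9 to 362 without 1 array. Diabetes hearts with age (1030) gave 477 with the erythroid covariate, 264 without diabetes 2 and 3, 189 with the arrays compared alone, 1868 at an adjusted p below 0.10, 332 with a 1.5-fold change added, 443 by the unadjusted rule and 347 to 1063 without 1 array. The arrays compared alone leave fewer samples, which does not account for the rise from 131 to 360 in control hearts. The causes of these moves were not tested.

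Lists called became 0 in all 5 contrasts with an estimated correlation. At E13.5 (2) they were 0 after quantile normalization, 4 with the erythroid covariate, 4 without diabetes 2 and 3, and 0 to 5 without 1 array. At E15.5 (4) they were 1 with the mean of all probe sets, 16 without either pair and 4 to 12 without 1 array, and the cell cycle list turned upward without diabetes 2 and 3 (adjusted p = 0.757). For the interaction (1) they were 2 with the erythroid covariate, 14 and 12 without the pairs and 1 to 9 without 1 array, with 4, 4, 5, 3, 2, 9, 2, 3, 8 and 2 without E13.5 control 1 and 2, E13.5 diabetes 2 and 3, E15.5 control 1, 2 and 3 and E15.5 diabetes 1, 2 and 3. For diabetes hearts with age (9) they were 5 without diabetes 2 and 3. At dim probe sets Vcan gave +0.13, +0.31 and +0.02, Kcnj5 −0.30 and Fech −0.093 in diabetes hearts with age. The causes were not tested.

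Replicate numbers did not pair the arrays: deviations of arrays with the same number correlated across genes at 0.06, 0.18 and 0.08 at E13.5 and at −0.07, −0.48 and −0.10 at E15.5. With replicate number as a block, 62 genes were called in control hearts with age and 860 in diabetes hearts.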

Other observations

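The permutation splits, the simulated changes and the stage correlations below were fixed before their results, and the tests of blood, of liver tissue, of Afp and of array pairs and the pools the stage correlations are held against were chosen after the result was seen. Lists not described so far had no call in the diabetes contrasts. Their median differences at E13.5 and E15.5 were −0.01 and 0.00 for cardiac transcription factors, 0.00 and −0.01 for neural crest and outflow genes, 0.00 and +0.07 for retinoic acid genes, −0.03 and +0.03 for apoptosis genes, −0.03 and −0.01 for IGF and insulin genes, +0.04 and −0.12 for immediate early genes, and −0.04 and −0.05 for atrial markers. They were +0.04 and +0.05 for smooth muscle markers, −0.10 and −0.03 for liver markers, +0.02 and 0.00 for neuron markers, and −0.24 and −0.60 for Y-linked genes. Among these lists, the median, the mean and the camera direction differed in sign for the retinoic acid genes at E13.5 and for the neural crest, IGF and insulin, liver and neuron lists at E15.5. Xist, a list of 1 gene, was too short to test.

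With age, cardiac transcription factor genes were not called as a list (median −0.06 in control and −0.16 in diabetes hearts, adjusted p = 0.30 and 0.33), while 2 of 24 fell in control and 5 in diabetes hearts. Smooth muscle markers split in diabetes hearts, where 3 of 10 rose and 2 fell. Ventricular markers had 1 of 10 lower in control and 3 in diabetes hearts. Glycolysis genes had 3 of 18 lower in diabetes hearts (median −0.06, adjusted p = 0.38).

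The E15.5 pools stood apart from each other in embryonic globins and liver genes. E15.5 diabetes replicate 2 had the lowest globins, and less blood as the whole source is argued against, since its 7 other red cell markers deviated from the other diabetes pools by a median of −0.30 against −3.42 for the embryonic globins, a gap of 3.12; whether the pool held somewhat less blood is not decided by that −0.30 (range −0.43 to 0.11, other arrays −0.01). A slightly older stage than diabetes replicates 1 and 3 may account for it. Outside the red cell list its deviation from them correlated across genes with the age effect in control hearts at r = 0.32. The E13.5 diabetes pools, which also share no array with that effect, gave −0.14 to 0.14. This r cannot tell an older replicate 2 from younger replicates 1 and 3, or a stage from a different mix of tissues, which was not tested. The mean of the fatty acid oxidation genes was 10.72 in diabetes replicate 2 and 10.55 and 10.58 in control replicates 1 and 3. It was 10.33 and 10.43 in diabetes replicates 1 and 3 and 10.24 in control replicate 2. On the first principal component, diabetes replicate 2 (26.1) lay apart from all of these. E15.5 control replicate 2 may be a younger pool, with r = −0.19 against the age effect in diabetes hearts (E13.5 control pools −0.05 to 0.07), but a younger stage does not account for its Afp, which lay 4.13 above the highest E13.5 array. Liver tissue carried into that pool is a candidate source, with 100% (7 of 7) of the liver markers other than Afp, Alb and Apoa2 above both other control pools, though 5 of the 7 were too dim to be tested and Ahsg (4.72) and Apob (3.98) were higher in some other array (5.01 and 4.03), and with Alb at 8.09, Ttr at 7.43 and Apoa1 at 5.76.

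Whether array number limited the count of 0 at E15.5 stays open, since 96% of simulated 2-fold changes were recovered with 200 genes changed at once and without the structure of these pools, while 30 genes measured here differed over 2-fold and none was called by limma (998 at an unadjusted value below 0.05). Whether the spread between pools apart in globins hid changes stays open: leaving out control replicate 2 and diabetes replicate 2 gave 48 called genes, against at most 2 for the 8 other pairs of 1 control and 1 diabetes array, but the arrays left were parted by embryonic globins between the conditions, so condition and globins cannot be told apart in them. Of the 10 splits of the 6 arrays, 2, the real one among them, gave at least its 998 genes at an unadjusted value below 0.05, and the highest other gave 2502. That split set control replicates 1 and 3 and diabetes replicate 2 against the rest, called 449 genes and follows the embryonic globins, which points to a structure of the samples. With 10 splits no share under 0.05 can be reached.

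At E13.5, all 10 splits gave at least the real 127 genes, with 795 in the highest other, and 10 splits are too few for a share under 0.05. For the interaction, 46 of 100 splits within the days, drawn from 200 and with the real one among them, gave at least the real 517 genes (highest other 2185), so chance cannot be excluded. For age, the real split called 131 genes in control and 1030 in diabetes hearts, 1 of 10 splits each, with 0 in the highest other, and again 10 splits are too few for a share under 0.05.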
